A study of Saccharomyces cerevisiae with 28 samples.

How the data were processed

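Total RNA of yeast was labelled with 1 dye, Cy3, and hybridised to 28 Agilent arrays, per the labels. RNA was extracted with a Fast RNA Pro Red kit and amplified and labelled with the Agilent Quick Amp kit, per the labels' protocols. The spot intensity values used here are those deposited as scanner output of Agilent Feature Extraction 10.7.3.1, which had subtracted the background and removed spatial trends within each array, per the file headers. No normalization between arrays is recorded in those headers. The authors' value table of the series holds linear intensity values whose column means are equal and whose medians lie between 2550 and 2594. It was therefore taken as scaled to a common distribution over all 28 arrays, but the method is not given in the sources used here. Its values correlated with the log2 scanner values of the same array with a lowest value of 0.982, it was not centred per gene, and it served as an alternative source.

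Every array's group came from its labels. There were 4 arrays in each of 5 groups and 8 untreated arrays, and the series' design text calls the samples independent biological samples. Adjusted p-values measure the spread between independent samples only if that holds for every array. The pair of arrays closest to each other, replicate 2 of the adsorbed fraction with UV and replicate 4 of the non-adsorbed fraction without UV, differed by 1.56 times the noise between spots. The lowest such ratio of any pair was 1.27, between untreated replicates 3 and 4, and 0 pairs of arrays were merged. Noise between spots of an array leaves out labelling and hybridisation, so these ratios cannot show that 2 arrays held different samples. The closest pair, of 2 different groups, correlated at 0.998, with 4 genes over 2-fold apart. That the samples are independent rests on the design text alone.

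The main values were log2 of the processed signal minus each array's 75th percentile over spots that are not controls. Control spots and 535 outlier spots were left out, 0 spots were saturated, and 38 probe values were missing. Each of the 6256 probes had 2 spots, which were averaged. A gene was kept where it was well above background on at least 4 of the 28 arrays, and the brightest probe stood for each systematic name, which left 5935 of 6225 names. The reference's gene table matched 5737 systematic names, 488 kept the name in the file, and 307 symbols were updated. No named gene had several probes. For a gene not well above background on any array of a group, a fold is given as a bound against the higher of its own signal and the dimmest probe above background on each array.

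All groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit with a group term, then eBayes with a trend), two-sided, and Benjamini-Hochberg adjusted over all genes tested in each comparison. The comparisons were: 5 groups against untreated yeast, the 2 fractions against each other with UV and without, each fraction with UV against UV only, and for each fraction the interaction of UV and TiO2. The test of gene lists was limma's camera with a preset correlation of 0.01 between genes over 41 lists of yeast regulons and complexes, adjusted over the lists within a comparison, and the same test with a correlation estimated from the data is given beside it. Camera called 144 of 451 tests with the preset correlation and 0 with the estimated one. A sentence on a list says that its genes rose or fell only where they passed in limma. Lists overlap in places, and their members were fixed from general knowledge of yeast.

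The groups, the tests of genes and lists, the lists, the alternatives named below and the rule for named genes were fixed before the data were examined. The 3 alternatives of first scan alone, without the closest pair of arrays and without the small slides were added after the data were seen, as were some tests of explanations. The rule named, against untreated yeast, the 8 largest increases and 8 largest decreases among called genes with a standard name, well above background on every array of 1 group and with no overlap between the groups. In comparisons of other groups it named 5 and 5, for interactions 5 and 5 without the overlap condition, and for each list described up to 4 members that passed or, where none did, up to 2 as values. The lists described in the report were chosen among the called lists after their values were seen. The display of HUG1, RNR3, COX1, COB, HO, GAR1, NOP1, BUD23, ATS1 and SHR5 on each array was chosen after their values were seen.

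Alternatives were normexp background correction with an offset of 50 (on the median spot signal, since some files lack the mean), quantile normalization, no filter or a filter at 24 arrays (5507 genes), the slide as a block, the replicate number as a block, fitting only the groups compared, the authors' table, the mean of all probes, and leaving out each array in turn. Slide and scan were read from the files. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots. The steps were tested on simulated data built on these arrays, with 100 genes changed by 1 and 100 by 2 on the log2 scale among 5935. For the adsorbed fraction with UV against untreated yeast 66% and 93% of them were recovered, with 5.36% false calls. For the adsorbed fraction without UV the shares were 62% and 95%, with 4.27% false calls, and on slide C alone 67% and 98%. Between the fractions with UV they were 38% and 89%. Of 41 lists, 1 was moved in the simulation and called, and 0 others were called. The simulated genes varied independently of each other and without slide effects. These shares therefore do not measure false calls that come from correlated genes or from slides in the real arrays.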

Results

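The series measured messenger RNA of Saccharomyces cerevisiae strain S288C, a laboratory yeast, after 8 h with or without titanium dioxide particles and UV light. The title gives the question as the effect of titanium dioxide nano-objects and their larger aggregates on yeast under irradiation. Arrays of 6 groups were compared. The adsorbed fraction and the non-adsorbed fraction of TiO2-treated yeast were each measured with UV and without UV (4 arrays each), beside yeast with UV only (4 arrays) and untreated yeast (8 arrays). Each of the 28 arrays held 1 sample, and 5935 genes were tested. The arrays lay on 5 slides, called A to E here, and in 2 scans. Slide C, the only slide of the second scan, held all 4 arrays of the adsorbed fraction without UV and 4 untreated arrays. Its 75th percentile of intensity was 659 to 4527, against 3670 to 9229 on the other slides, and between 86.8% and 95.6% of probes per array were well above background. The number of arrays limits the precision. Fold changes are on the log2 scale with standard errors, and a gene was called where its adjusted p from limma was below 0.05.

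In the adsorbed fraction without UV, genes of ribosome assembly fell and genes of the general stress response rose relative to untreated yeast (4 against 8 arrays). The largest decreases were those of GAR1 (YHR089C; -3.99 ± 0.53, adjusted p = 4.4e-05) and NOP1 (YDL014W; -3.51 ± 0.56), protein components of the small nucleolar particles that modify ribosomal RNA. BUD23, a methyltransferase of ribosomal RNA, fell by 3.23 and was followed by ATS1 (-2.61), the glucose repressor MIG2 (-2.58), the glucose transporter HXT3 (-2.55), SHR5 (-2.41) and the transporter HXT1 (-2.28). The largest increases were EGO4 (3.08 ± 0.45, adjusted p = 1.1e-04), PHM7 (2.86), PNS1 (2.60 ± 0.32, adjusted p = 2.0e-05), the stress-induced repressor XBP1 (2.59), SOL4 (2.57), the kinases MRK1 (2.55) and RCK1 (2.54), and GID11 (2.52). No overlap between the arrays of the 2 groups was a condition for naming these 16 genes, so they are the largest changes among such genes only. BUD23, ATS1 and SHR5 were not low in this group alone. Replicates 1 and 3 of UV only and replicate 2 of the non-adsorbed fraction with UV reached similar intensities. BUD23 stood at -3.11 to -2.97, ATS1 at -3.26 to -2.75 and SHR5 at -3.12 to -2.17 on those arrays. In this group they stood at -3.88 to -2.76, -3.37 to -2.61 and -2.77 to -2.17.

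Limma called 984 genes in this comparison, 465 higher and 519 lower, of which 197 and 213 changed at least 2-fold. Within slide C alone, where both groups had 4 arrays, 1326 genes were called, 716 higher and 610 lower. The changes there were -3.30 for GAR1, -3.47 ± 0.21 for NOP1 and 2.70 ± 0.20 for PNS1. With the slide as a block the count was 1380. After normexp correction it was 679, with 493 higher and 186 lower. Leaving out replicate 2 of the treated group lowered the count to 229.

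Of 88 measured genes of ribosome biogenesis, 52 fell and none rose (74 fell when adjusted over the list alone), with a median of -1.05 (camera adjusted p = 2.7e-22, adjusted p = 0.965 with an estimated correlation). Besides GAR1 and NOP1 these included RIX1 (-1.79) and CBF5 (-1.88, and -0.63 on slide C). Within slide C, 79 of them fell, with a median of -1.16. RNA polymerase I and III subunits, which transcribe ribosomal and transfer RNA, had 12 members that fell among 21 (16 adjusted over the list alone, median -0.79, camera adjusted p = 1.4e-07, adjusted p = 0.965 with an estimated correlation). RPC37 (-1.27, and -0.58 on slide C), RPA43 (-1.25) and RPC53 (-1.17) were among them. Of 136 cytosolic ribosomal protein genes, 1 passed, RPS6A (-1.02, and -0.53 on slide C), although the list's median was -0.52 (camera adjusted p = 1.6e-05, adjusted p = 0.965 with an estimated correlation; 0 genes adjusted over the list alone). On slide C, 19 of them fell and 2 rose (1 and 0 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 9.1e-12, adjusted p = 0.834 with an estimated correlation).

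The Msn2/4 list of general stress genes had 17 members that rose and none that fell among 35 (21 rose when adjusted over the list alone), with a median of 0.90 (camera adjusted p = 2.3e-10, adjusted p = 0.965 with an estimated correlation). RTN2 (2.46) and SPI1 (2.27) rose with XBP1 and SOL4. On slide C, 24 of these genes rose, with a median of 1.18. In the Aft1 iron regulon, genes of iron uptake, 5 of 25 rose (5 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 9.7e-04, adjusted p = 0.965 with an estimated correlation). FIT3, a cell wall mannoprotein of siderophore iron retention, rose by 1.74, SMF3 by 1.01 and COT1 by 0.83 (0.41 on slide C). Within slide C, 12 of the list rose. Of 26 genes of the G1/S transition, 9 fell (9 adjusted over the list alone, median -0.58, camera adjusted p = 7.1e-04, adjusted p = 0.965 with an estimated correlation), among them DPB2 (-1.06), a subunit of DNA polymerase epsilon.

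Smaller shifts concerned carbon metabolism and autophagy. MDH2 (1.59) and CIT2 (1.54) of gluconeogenesis and the glyoxylate cycle rose (2 adjusted over the list alone; list median 0.49, and 0.27 without replicate 1 of the untreated group), and ADH1 (-1.26) and PDC1 (-0.86, and -0.42 on slide C) of fermentation fell while 1 gene of that list rose (2 and 1 adjusted over the list alone). ATG8 of autophagy rose by 0.96 (0 genes adjusted over the list alone). The camera adjusted p was 0.0186 for gluconeogenesis, 0.0355 for glycolysis and fermentation and 0.0114 for autophagy, and the adjusted p was 0.965 for all 3 with an estimated correlation. In DNA repair, 6 of 28 genes fell (9 adjusted over the list alone), among them OGG1 (-0.98), a DNA glycosylase. The list's median was -0.18 (camera adjusted p = 0.043, adjusted p = 0.965 with an estimated correlation), but 0.11 after normexp background correction, and it was -0.038 and -0.36 without replicates 1 and 4 of the treated group and -0.34 and -0.069 without untreated replicates 2 and 8. On slide C the DNA repair list was not called (median -0.0015, camera adjusted p = 0.623, adjusted p = 0.947 with an estimated correlation), with 4 genes that fell (2 adjusted over the list alone). Gluconeogenesis (median 0.39, camera adjusted p = 0.137, adjusted p = 0.834 with an estimated correlation) and glycolysis and fermentation (median -0.37, camera adjusted p = 0.0722, adjusted p = 0.865 with an estimated correlation) were not called there either, although 5 genes of the former rose (5 adjusted over the list alone). Autophagy was called on slide C, with 7 genes that rose (9, and 1 that fell, adjusted over the list alone; camera adjusted p = 0.00222, adjusted p = 0.424 with an estimated correlation).

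**Figure D1:**
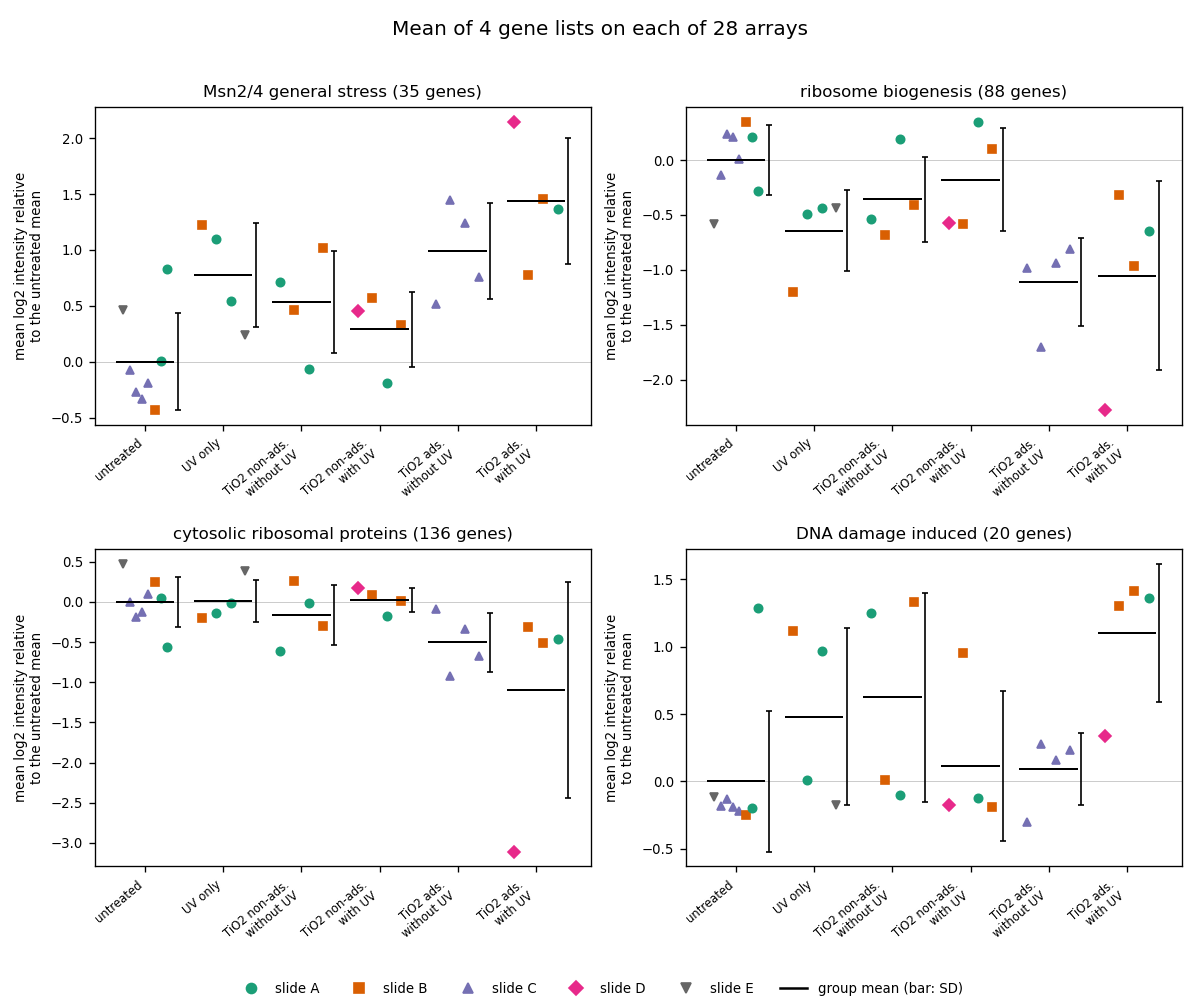
Mean log2 intensity of 4 gene lists on each of 28 arrays, relative to the untreated mean (vertical axes), by group (horizontal axes). Each point is 1 array with its slide as colour and shape, lines are group means and bars are SDs; replicate 1 of the adsorbed fraction with UV lay at -3.11 for cytosolic ribosomal proteins, against -0.51 to -0.31 on the other 3 arrays of its group.

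In the adsorbed fraction with UV, oxidative and general stress genes rose and genes of ribosomes, histones and cell division fell relative to untreated yeast (4 against 8 arrays). OYE3 (YPL171C), an NADPH oxidoreductase, rose most among the genes whose arrays did not overlap (3.17 ± 0.55, 8.98-fold, adjusted p = 0.0027). It was followed by FMP16 (2.73 ± 0.56), the cell wall protein SPI1 (2.11), EGO4 (1.91), the mitochondrial carrier PIC2 (1.90), SUE1 (1.89) and IDP2 (1.85), the cytosolic isocitrate dehydrogenase. SPS22, which also rose, was not well above background on any untreated array, so it has no rank among these. It was at least 1.74-fold higher with treatment (adjusted p = 0.00409), but its log2 change was -0.27 after normexp background correction. The largest decreases without overlap were those of the transcription factor SFG1 (-2.41 ± 0.58, adjusted p = 0.00616), NFG1 (-1.95), the cell wall enzyme UTR2 (-1.87), LIA1 (-1.80), the RNA helicase HAS1 (-1.80), the polymerase I subunit RPA49 (-1.71) and the ribosomal proteins RPL14A and RPS18B (-1.70 and -1.70).

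Limma called 1792 genes here, 1061 higher and 731 lower, of which 467 and 349 changed at least 2-fold. The median change of all genes was 0.10, against 0.01 after quantile normalization, where 851 genes were higher and 898 lower, and 897 were higher and 942 lower in the authors' table. No gene was called by limma with the slide as a block (1191 at an unadjusted p below 0.05) or on the arrays of the first scan alone (1530), nor within slide A (28; 1 against 2 arrays) or slide B (1334; 2 against 1), where so few arrays say nothing about stability. The count was 855 after normexp correction (389 higher and 466 lower), 833 when only these groups were fitted, and 683 without replicate 1 of the treated group.

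The Msn2/4 list had 29 of 35 genes that rose and none that fell (33 rose when adjusted over the list alone), with a median of 1.27 (camera adjusted p = 2.2e-13, adjusted p = 0.422 with an estimated correlation). PAI3 (3.03), MOH1 (3.02), NQM1 (2.75) and the aldehyde dehydrogenase ALD3 (2.32) rose most in it. Its median was 0.86 with the slide as a block, 0.86 within slide A and 1.32 within slide B. Of 34 Yap1 and Skn7 genes of the oxidative stress response, 14 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.56, camera adjusted p = 0.00139, adjusted p = 0.422 with an estimated correlation), among them the glutathione transferase GTT2 (2.00), the peroxiredoxin TSA2 (1.82) and AAD6 (1.67). The median of that list was 0.31 with the slide as a block, 0.40 and 0.35 within slides A and B, and 0.32 without replicate 1. Chaperone genes of the Hsf1 list rose in 13 of 25 cases (14 adjusted over the list alone), with HSP42 (1.72), MBF1 (1.63) and HSP104 (1.57) as the largest. Their median was 0.95 (camera adjusted p = 0.003, adjusted p = 0.564 with an estimated correlation), 0.43 with the slide as a block, 0.65 and 0.25 within slides A and B, and 0.47 without replicate 1. Untreated replicate 8 had a higher Msn2/4 mean than treated replicate 2 (0.83 against 0.78). In the Hsf1 list untreated replicate 1 (1.24) exceeded treated replicates 2 to 4 (0.24 to 0.69). All arrays of slides D and E, which include treated replicate 1, stood at 1.24 to 1.66 in that list. No other array of any group stood above 0.69. The Yap1 and Skn7 means did not overlap between these 2 groups (0.38 to 1.06 treated, -0.10 to 0.21 untreated). Arrays of other groups reached the treated range. Replicate 4 of the non-adsorbed fraction without UV (0.413) and replicate 1 of UV only (0.386) lay above treated replicate 2 (0.381).

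Of 136 cytosolic ribosomal protein genes, 91 fell and none rose (106 fell when adjusted over the list alone), with a median of -1.17 (camera adjusted p = 6.8e-27, adjusted p = 0.422 with an estimated correlation). RPP2A (-1.81), RPS10A (-1.76) and RPL33B (-1.76) fell most. Without replicate 1 the median was -0.44, and it was -0.80 with the slide as a block, -0.25 within slide A and -0.69 within slide B. In ribosome biogenesis, 64 of 88 genes fell and none rose (74 fell adjusted over the list alone, median -1.12, camera adjusted p = 6.2e-23, adjusted p = 0.422 with an estimated correlation), with NOG1 (-2.02), RRP1 (-1.76) and DBP3 (-1.67) beside HAS1. That median was -0.65 without replicate 1, -0.67 with the slide as a block, and -0.64 and -0.98 within slides A and B. RNA polymerase I and III subunits fell in 10 of 21 cases (11 adjusted over the list alone), RPA34 (-1.54) and RPA190 (-1.31) among them. Their median of -0.71 (camera adjusted p = 6.9e-05, adjusted p = 0.422 with an estimated correlation) was -0.29 without replicate 1 and -0.39 with the slide as a block (-0.34 and -0.72 within slides A and B). The means of these lists overlapped between the groups array by array. Untreated replicate 8 stood at -0.56 in ribosomal proteins, against -0.51 to -0.31 on treated replicates 2 to 4. Untreated replicate 1 stood at -0.59 in ribosome biogenesis and -0.200 in polymerase subunits, against -0.32 and -0.195 on treated replicate 2.

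Histone genes fell in 9 of 11 cases (10 adjusted over the list alone), led by HTB2 (-2.19) and HTA2 (-1.93), which encode histones H2B and H2A. The list median was -0.98 (camera adjusted p = 1.8e-05, adjusted p = 0.422 with an estimated correlation), -0.73 with the slide as a block, and -0.39 and -1.41 within slides A and B. The mean of the list on untreated replicate 8 (-1.19) and on replicates 1 and 4 of the non-adsorbed fraction without UV (-1.36 and -0.99) lay within the range of the treated arrays (-1.38 to -0.92), so these genes did not separate the groups array by array. Of 18 G2/M genes, 10 fell (11 adjusted over the list alone, median -0.58, camera adjusted p = 8.2e-05, adjusted p = 0.422 with an estimated correlation), including the mitotic cyclins CLB2 (-1.27) and CLB1 (-1.21) and the kinase CDC5 (-1.08). With the slide as a block that median was -0.68, and within slides A and B it was -0.42 and -0.82. The mean of the G2/M list was -0.30 on untreated replicate 8 and -0.35 to 0.53 on the other untreated arrays. On replicates 1 and 4 of the non-adsorbed fraction without UV it was -0.494 and -0.498, within the range of the treated arrays (-0.79 to -0.47). In cell separation and adhesion, 8 of 17 genes fell and 3 rose (12 and 3 adjusted over the list alone), with DSE2 (-2.45), EGT2 (-2.37) and SCW11 (-2.02) of daughter cell separation lowest (list median -0.76, camera adjusted p = 0.00384, adjusted p = 0.422 with an estimated correlation, -0.85 with the slide as a block, -0.61 and -1.07 within slides A and B). The same 3 arrays of other groups stood at -0.69, -0.82 and -0.60 in that list, against -0.76 to -0.60 on the treated arrays and -0.038 to 0.28 on the other untreated arrays. G1/S genes fell in 5 of 26 cases (5 adjusted over the list alone), the cyclin CLN1 by 1.54. Their median of -0.42 (camera adjusted p = 8.3e-04, adjusted p = 0.477 with an estimated correlation) was -0.07 without replicate 1 and -0.26 with the slide as a block (-0.15 and -0.10 within slides A and B).

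Of 20 genes induced by DNA damage, 12 rose and none fell (16 rose when adjusted over the list alone), with a median of 0.91 (camera adjusted p = 1.1e-04, adjusted p = 0.435 with an estimated correlation). The ribonucleotide reductase genes RNR3 (2.89 ± 0.93, adjusted p = 0.0233) and RNR4 (1.32) and the ubiquitin gene UBI4 (1.14) were among them. The median was 0.67 with the slide as a block, 0.52 within slide A and 1.16 within slide B. These genes did not separate the groups array by array. RNR3 stood at 1.06 to 1.41 on 3 arrays of this group and at -1.83 on replicate 1, while untreated replicate 8 stood at 1.26 and the other untreated arrays at -3.53 to -2.52. HUG1, another gene of that list whose fitted change of 3.79 did not pass (adjusted p = 0.0899), stood at -0.60 to -0.12 on replicates 2 to 4 of this group and at -9.04 on replicate 1. It was not well above background on that array or on 6 of the 8 untreated arrays, so such low values are not exact. On untreated replicate 8 HUG1 stood at -0.66, against -8.95 to -5.65 on the other untreated arrays, and it was chosen for display after its values were seen.

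**Figure D2:**
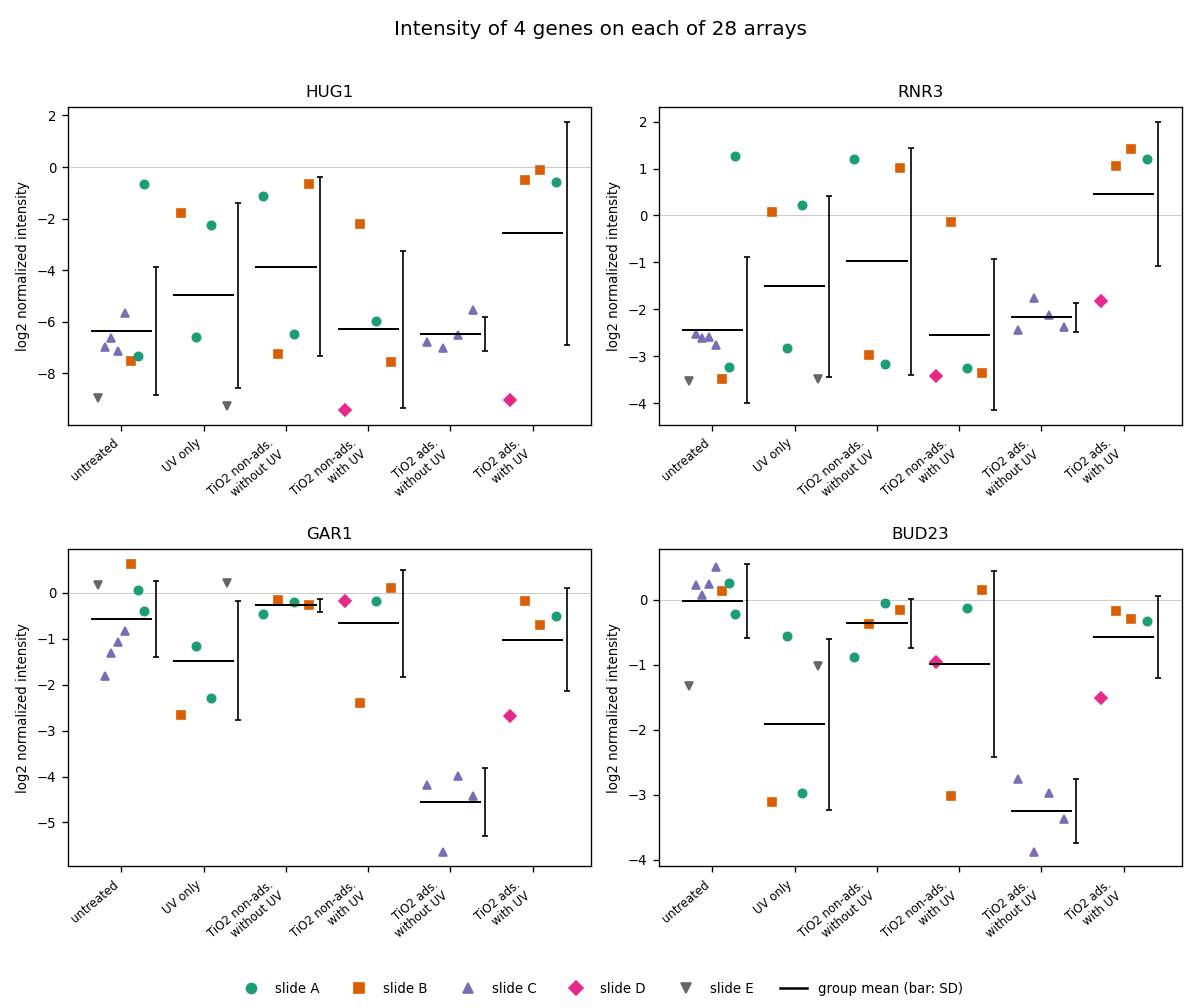
Log2 normalized intensity of HUG1, RNR3, GAR1 and BUD23 on each of 28 arrays (vertical axes), by group (horizontal axes). Each point is 1 array with its slide as colour and shape, lines are group means and bars are SDs. HUG1 and RNR3 were high on single arrays of several groups, including untreated replicate 8. GAR1 and BUD23 were low on all 4 arrays of the adsorbed fraction without UV. BUD23 was about as low on replicates 1 and 3 of UV only and replicate 2 of the non-adsorbed fraction with UV.

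Metabolic and turnover genes also rose in the adsorbed fraction with UV. Peroxisome and beta-oxidation genes rose in 12 of 23 cases (12 adjusted over the list alone, median 0.67, camera adjusted p = 1.1e-04, adjusted p = 0.422 with an estimated correlation, 0.41 with the slide as a block, 0.32 and 0.56 within slides A and B), with the carnitine acetyltransferase CAT2 (2.05) and the thiolase POT1 (2.01) highest. Autophagy and vacuolar proteolysis had 13 of 20 genes that rose (14 adjusted over the list alone, median 0.77, camera adjusted p = 2.2e-04, adjusted p = 0.422 with an estimated correlation, 0.44 with the slide as a block, 0.46 and 0.63 within slides A and B), including ATG29 (1.95, but -0.068 after normexp correction) and the kinase ATG1 (1.79). The drug efflux list rose in 10 of 18 genes and fell in 1 (11 and 1 adjusted over the list alone, median 0.67, camera adjusted p = 0.003, adjusted p = 0.435 with an estimated correlation, 0.44 with the slide as a block, 0.16 and 0.61 within slides A and B), with RSB1 (2.51) and the transporter PDR5 (1.39). Proteasome genes rose in 11 of 36 cases (14 adjusted over the list alone, median 0.37, camera adjusted p = 7.3e-04, adjusted p = 0.444 with an estimated correlation), although the median was 0.15 with the slide as a block (0.20 and 0.26 within slides A and B) and RPN3, its largest member at 1.25, was then at -0.035. Amino acid biosynthesis genes under Gcn4 fell in 7 of 42 cases and rose in 1 (4 and 0 adjusted over the list alone), led by LEU9 (-1.54). The list median of -0.56 (camera adjusted p = 2.3e-04, adjusted p = 0.477 with an estimated correlation) was -0.21 without replicate 1 and -0.45 with the slide as a block (-0.20 and -0.47 within slides A and B). Untreated replicate 8 had higher means than treated replicate 2 in peroxisome (0.466 against 0.462), autophagy (0.59 against 0.40), drug efflux (0.48 against 0.31) and proteasome genes (0.41 against 0.36). In the Gcn4 list untreated replicate 1 stood at -0.70, against -0.17 to -0.11 on treated replicates 2 to 4. The arrays of slides D and E, from different groups, stood at -1.40 to -0.60 in that list, and no other array below -0.34.

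With UV only, no single gene passed against untreated yeast (4 against 8 arrays; 0 genes by limma, 1306 at an unadjusted p below 0.05), but stress and ribosome lists shifted. The Msn2/4 list had a median of 0.81 (camera adjusted p = 5.5e-08, adjusted p = 0.961 with an estimated correlation), and 18 of its 35 genes rose when adjusted over the list alone. SOL4 stood at 1.43 ± 0.45 (adjusted p = 0.157). Ribosome biogenesis had a median of -0.68 (camera adjusted p = 2.7e-19, adjusted p = 0.961 with an estimated correlation), with 17 of 88 genes lower when adjusted over the list alone. NOP1 stood at -1.67 and REI1 at -1.68. The intensity of NOP1 was -2.35 and -1.92 on replicates 1 and 3 of UV only but 0.50 and 0.35 on replicates 2 and 4, against an untreated mean of 0.82. The Hsf1 chaperones had a median of 0.59 (camera adjusted p = 7.0e-04, adjusted p = 0.961 with an estimated correlation; 0 genes adjusted over the list alone), HSP104 at 1.45. These 3 medians with the slide as a block were 0.57, -0.53 and 0.27. Within slide A they were 0.39, -0.42 and 0.24, and within slide B 1.64, -1.50 and 0.33. In the Hsf1 list the mean of replicate 4 of UV only, on slide E, was 1.48, against 0.30 to 0.54 on its other replicates. The untreated array of slide E stood at 1.24. Without untreated replicate 1, 697 genes were called, without replicate 4 of UV only 1 gene (YMR206W, 3.22 ± 0.56), and without the 2 small slides 642.

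The non-adsorbed fraction with UV showed no called gene against untreated yeast (4 against 8 arrays; 0 genes by limma, 560 at an unadjusted p below 0.05). Zinc-responsive genes of the Zap1 list had a median of -0.42 (camera adjusted p = 0.0135, adjusted p = 0.98 with an estimated correlation; none of 18 passed over the list alone), with ZPS1 at -2.61 ± 1.26 and VEL1 at -2.12 ± 0.88 (adjusted p = 0.507 for both). That median was -0.13 with the slide as a block, -0.02 and -0.28 within slides A and B, and -0.25 without either of replicates 1 and 2 of the fraction. The mean of the Zap1 list was -1.04 to -0.93 on all arrays of slides D and E, whatever their group, and -1.01 on replicate 2 of the fraction. The Msn2/4 list had a median of 0.36 and ribosome biogenesis -0.19 (camera adjusted p = 0.0356 and 0.0135, adjusted p = 0.98 for both with an estimated correlation). Both signs turned with the slide as a block, to -0.13 and 0.24, and the slides themselves differed in sign (-0.56 and 0.40 within slide A, 0.85 and -0.56 within slide B). Without replicate 1 of the fraction the Msn2/4 median was 0.22. The ribosome biogenesis median was -0.086, -0.049, -0.37 and -0.30 without replicates 1 to 4 of the fraction and -0.30 without untreated replicate 1.

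The non-adsorbed fraction without UV had no called gene either (4 against 8 arrays; 0 genes by limma, 604 at an unadjusted p below 0.05). Its Msn2/4 median was 0.47 (camera adjusted p = 1.7e-06, adjusted p = 0.831 with an estimated correlation), with PAI3 at 1.39 ± 0.57. Ribosome biogenesis had a median of -0.36 (camera adjusted p = 8.3e-10, adjusted p = 0.831 with an estimated correlation) and -0.57 without replicate 3. The DNA damage list had a median of 0.49 (camera adjusted p = 7.6e-04, adjusted p = 0.831 with an estimated correlation) and 0.32 without replicate 1, with RNR3 at 1.46 ± 0.93. HUG1 stood at -1.13 and -0.64 on replicates 1 and 4 and at -7.24 and -6.47 on replicates 2 and 3. No member of these 3 lists passed over its list alone. The 3 medians with the slide as a block were 0.26, -0.25 and 0.20. Within slide A they were -0.06, -0.07 and 0.02, and within slide B 1.21, -0.89 and 0.76.

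Between the adsorbed and the non-adsorbed fraction with UV (4 against 4 arrays), genes of division and ribosomes were lower and stress genes higher in the adsorbed fraction. RRT1 (3.09 ± 0.65, adjusted p = 0.0232), MOH1 (3.04), SHH3 (3.01), OYE3 (2.98 ± 0.64) and the cell wall protein PIR3 (2.82) were the most increased. AI5_ALPHA, encoded in an intron of mitochondrial COX1, was lowest (-3.60 ± 0.97), then HO (-3.49 ± 0.71), SFG1 (-3.17), SPS4 (-3.09) and EGT2 (-2.41). Of 18 G2/M genes, 7 fell (12 adjusted over the list alone, median -0.84, camera adjusted p = 5.7e-10, adjusted p = 0.343 with an estimated correlation), including CLB1 (-1.68), BUD4 (-1.64) and CDC5 (-1.49). Histones fell in 4 of 11 cases (10 adjusted over the list alone, median -1.13, camera adjusted p = 2.1e-06, adjusted p = 0.343 with an estimated correlation), HTB2 by 2.18. Each slide held equal numbers of the 2 fractions, so the slide as a block cannot change these medians. They were -0.71 and -1.01 within slide A and -0.76 and -1.002 within slide B.

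In the same comparison the Msn2/4 list had 12 genes that rose among 35 (22 adjusted over the list alone, median 1.08, camera adjusted p = 4.0e-11, adjusted p = 0.343 with an estimated correlation). Within slides A and B its medians were 1.45 and 0.64. The Yap1 and Skn7 list had 8 of 34 (11 adjusted over the list alone, median 0.55, camera adjusted p = 6.0e-05, adjusted p = 0.343 with an estimated correlation, 0.58 and 0.19 within slides A and B), TSA2 at 1.69 among them. Cytosolic ribosomal protein genes fell in 24 of 136 cases (111 adjusted over the list alone), RPL9A by 1.77. Their median of -1.16 (camera adjusted p = 6.7e-31, adjusted p = 0.353 with an estimated correlation) was -0.46 without replicate 1 of the adsorbed fraction, and -0.34 and -0.47 within slides A and B. PDR5 (1.53) and ATG8 (1.83) rose as well. Limma called 472 genes, 291 higher and 181 lower (254 and 234 after quantile normalization, 279 and 279 in the authors' table). The count was 1572 with the slide as a block, 119 after normexp correction and 123 when only these groups were fitted. It was 0 on the first scan alone (1748 at an unadjusted p below 0.05) and 0 without the small slides (1395). The calls on the first scan ended without a change in fold: the 472 genes had a median size of 1.13 in both fits, with a standard error of 0.31 before and 0.32 after. Without the small slides they kept a median of 84.5% of their change (median size 0.90). Their standard error of 0.30 was no larger than before, so the change was smaller, and what fewer arrays added was not tested. No gene was called by limma within slide A (448; 1 against 1 array) or slide B (843; 2 against 2), where so few arrays say nothing about stability. Leaving out single arrays of the adsorbed fraction gave 47, 857, 0 and 243 genes for replicates 1 to 4, and of the non-adsorbed fraction 113, 0 and 158 for replicates 1, 3 and 4.

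Between the 2 fractions without UV (4 against 4 arrays), the transporter gene HXT17 (3.53 ± 0.67, adjusted p = 0.00173), RCK1 (2.99 ± 0.36, adjusted p = 2.7e-05), the mitochondrial gene COB (2.92), PRY3 (2.88) and SRL1 (2.54) were most increased in the adsorbed fraction. COB stood at -3.74 and -3.64 on replicates 1 and 4 of the non-adsorbed fraction and at -0.90 and -1.45 on replicates 2 and 3. On the adsorbed arrays it stood at -0.25 to 1.58, against -0.55 to 0.81 on the untreated arrays of slide C. GAR1 (-4.29 ± 0.62, adjusted p = 2.1e-04), CIN4 (-3.73), NOP1 (-3.47), MTC3 (-3.24) and BUD23 (-2.88) were most decreased. Ribosome biogenesis fell in 17 of 88 genes (17 adjusted over the list alone, median -0.62, camera adjusted p = 2.8e-06, adjusted p = 0.971 with an estimated correlation, -0.90 with the slide as a block). The Aft1 list had 3 of 25 genes that rose (3 adjusted over the list alone, median 0.48, camera adjusted p = 0.00801, adjusted p = 0.971 with an estimated correlation, 0.74 with the slide as a block), FIT3 by 1.94. Proteasome genes fell in 8 of 36 cases (9 adjusted over the list alone, median -0.37, camera adjusted p = 0.00267, adjusted p = 0.971 with an estimated correlation), PUP2 by 2.36, and their median was 0.02 with the slide as a block.

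Limma called 1061 genes between these fractions, 420 higher and 641 lower. No slide held both groups and the main fit had no slide term, so these calls cannot be told apart from slide and scan. With the slide as a block, the groups were linked only through the untreated arrays. The count was then 49 and SRL1 stood at -0.15. The 1061 genes kept a median of 41.2% of their change there (lower quartile 14.2%), and 908 kept their sign. Normexp correction gave 605 genes, 434 higher and 171 lower. Without replicate 2 of the adsorbed fraction the count was 415, and without replicates 1, 3 or 4 of the non-adsorbed fraction it was 700, 698 or 565.

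Against UV only (4 against 4 arrays), the adsorbed fraction with UV had 1 called gene, BUD4 of bud site selection (-1.78 ± 0.31, adjusted p = 0.0345; 1169 genes at an unadjusted p below 0.05). OYE3 stood at 2.63 ± 0.64 and MOH1 at 2.62 ± 0.66 (adjusted p = 0.0687 for both). The G2/M list had 14 of 18 genes that fell when adjusted over the list alone, with a median of -1.12 (camera adjusted p = 5.2e-13, adjusted p = 0.141 with an estimated correlation), -1.03 with the slide as a block, and -0.87 and -0.82 within slides A and B. Histones fell in 9 of 11 cases adjusted over the list alone (median -0.90, camera adjusted p = 5.3e-06, adjusted p = 0.374 with an estimated correlation, -0.84 with the slide as a block, -0.87 and -0.76 within slides A and B). Cytosolic ribosomal protein genes had a median of -1.15 (camera adjusted p = 8.6e-36, adjusted p = 0.419 with an estimated correlation; 110 of 136 fell adjusted over the list alone), -0.45 without replicate 1 of the fraction, -0.74 with the slide as a block, and -0.40 and -0.24 within slides A and B. BUD4 was not called with the slide as a block or on the first scan alone (0 genes by limma, 1115 and 1213 at an unadjusted p below 0.05), but its fold stayed about as large, at -1.67 ± 0.33 and -1.78 ± 0.33. Its adjusted p was 0.0176 to 0.121 over the alternatives. Nor was it called without the small slides (-1.58 ± 0.35), where NIT1 was the 1 gene called (1.19 ± 0.20; 797 at an unadjusted p below 0.05). The count was 0 without any 1 of replicates 3 and 4 of the fraction or of the 4 UV arrays, 2 without replicate 1 of the fraction (SWI1 at -1.35 ± 0.25 and YCH1 at 1.40 ± 0.25, not BUD4), 187 without its replicate 2, and 79 in the authors' table.

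The non-adsorbed fraction with UV had no called gene against UV only (4 against 4 arrays; 0 genes by limma, 20 at an unadjusted p below 0.05). Ribosome biogenesis was higher, with a median of 0.50 and 87 of 88 genes above 0 (camera adjusted p = 5.3e-37, adjusted p = 0.764 with an estimated correlation), and the Msn2/4 list was lower, with a median of -0.51 (camera adjusted p = 5.7e-12, adjusted p = 0.764 with an estimated correlation). SOL4 stood at -0.85 ± 0.52 and TSL1, of trehalose synthesis, at -0.80 ± 0.51. With the slide as a block the medians were 0.79 and -0.70. They were 0.87 and -1.09 within slide A, and 0.96 and -0.83 within slide B. Without replicate 3 of the fraction they were 0.29 and -0.33. The ribosome biogenesis median was also 0.33 without replicate 1 of UV only, and the Msn2/4 median -0.33 without its replicate 2. No member of either list passed over its list alone. The groups overlapped array by array, so 87 of 88 genes above 0 does not mean that the arrays separated. Ribosome biogenesis means were -0.57, -0.58, 0.35 and 0.10 on replicates 1 to 4 of the fraction. They were -1.20, -0.49, -0.44 and -0.43 on those of UV only. Msn2/4 means were 0.45, 0.57, -0.19 and 0.33 on the former and 1.22, 1.09, 0.54 and 0.24 on the latter. Within slide A alone (1 against 2 arrays) GSR1 stood at -4.04. A fit with 1 array in a group takes its spread from other groups, so counts within slides A and B say nothing about stability.

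The interaction asked whether the change from untreated yeast to the adsorbed fraction differed with UV from that without UV, UV only being the reference under irradiation (4, 4, 4 and 8 arrays). BUD23 (4.57 ± 0.74, adjusted p = 0.00109), GAR1 (4.45 ± 0.82), SHR5 (4.32), ATS1 (4.29) and HXT3 (4.22) had the most positive terms. WSC4 (-3.72 ± 0.77), HXT17 (-3.60), RPI1 (-3.58), MRK1 (-3.18) and PRY3 (-3.17) had the most negative. In the G2/M list, 8 of 18 genes had a negative term that passed (11 adjusted over the list alone), CLB2 at -2.01 and CDC5 at -1.70 among them. The list median was -1.08 (camera adjusted p = 2.3e-08, adjusted p = 0.289 with an estimated correlation) and -1.29 with the slide as a block. Ribosome biogenesis had a median of 0.61, with 3 genes past the threshold over all genes and 3 over the list alone, NOP19 (1.31) among them (camera adjusted p = 6.2e-06, adjusted p = 0.895 with an estimated correlation). That median was 1.01 with the slide as a block, 0.37 without replicate 2 of the adsorbed fraction with UV, 1.08 without its replicate 1 and 0.38 without replicate 2 of the adsorbed fraction without UV. BUD23 stood at -3.11 and -2.97 on replicates 1 and 3 of UV only and at -0.57 and -1.02 on replicates 2 and 4. On replicates 1 to 4, SHR5 stood at -2.17, 0.15, -3.12 and -0.09, and ATS1 at -2.75, -0.68, -3.26 and -0.66. Low values on UV only add to the positive terms of these genes. The adsorbed fraction without UV lay only on slide C, which held no array with UV. Limma called 261 genes, 140 positive and 121 negative (39 and 60 after normexp correction), and 773 with the slide as a block. The count was 593, 158, 127 and 117 without replicates 1 to 4 of the adsorbed fraction with UV, 98 and 152 without replicates 2 and 4 of that without UV, and 113 and 128 without replicates 1 and 3 of UV only.

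For the non-adsorbed fraction no gene had an interaction that passed (4, 4, 4 and 8 arrays; 0 genes by limma, 422 at an unadjusted p below 0.05). The Msn2/4 list had a median of -0.99 (camera adjusted p = 1.5e-11, adjusted p = 0.783 with an estimated correlation), with PAI3 at -1.90 ± 0.86 and the catalase gene CTT1 at -1.89 ± 0.59. Ribosome biogenesis had a median of 0.86 (camera adjusted p = 1.4e-25, adjusted p = 0.783 with an estimated correlation), REI1 at 1.91 ± 0.76. With the slide as a block these medians were -1.02 and 1.07, and no member of either list passed over its list alone.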

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

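Of the tests in this part, those of the untreated arrays of the second scan and of the percentile scaling, and all 3 of the HUG1 pattern, were chosen after the result was seen, as were the 14 lists and 10 genes searched for single arrays that stand apart; the tests of array row, of dimmer arrays and of other splits, except the splits within slide C, were chosen before.

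Single arrays stood apart from the others of their group in 23 of 162 groups of values, a share that cannot be set against chance because the genes and lists were chosen after their values were seen. Replicate 1 of the adsorbed fraction with UV, on slide D, had the lowest mean of cytosolic ribosomal proteins (-3.11 relative to the untreated mean, others -0.51 to -0.31), histones (-1.38), G1/S genes (-1.70) and DNA damage genes (0.34, others 1.31 to 1.41), and the lowest HUG1 (-9.04), RNR3 (-1.83) and BUD23 (-1.51). Untreated replicate 8 was highest in DNA damage genes (1.29), peroxisome genes (0.47), HUG1 (-0.66, others -8.95 to -5.65) and RNR3 (1.26), and lowest in histones (-1.19) and HO (-2.88). Replicate 2 of the non-adsorbed fraction with UV was highest in DNA damage genes (0.95) and RNR3 (-0.13) and lowest in GAR1 (-2.40), ATS1 (-3.09) and SHR5 (-2.93). Untreated replicate 1 was highest in Hsf1 chaperones (1.24) and lowest in BUD23 (-1.33). All arrays of slides D and E, from different groups, stood at 1.24 to 1.66 in Hsf1 chaperones, and no other array above 0.69. That level thus goes with these slides. Replicate 1 of UV only was lowest in ribosome biogenesis (-1.20), and replicate 4 of the adsorbed fraction without UV was lowest in SHR5 (-2.77). The SD between spots of a probe was 0.478 on replicate 3 of the non-adsorbed fraction with UV, against 0.0717 to 0.0941 on the other 3 of its group, which lay on slides B and D. It was 0.161 to 0.478 on slide A, 0.180 to 0.283 on slide C and at most 0.0998 on slides B, D and E, so it goes with the slide. The change with the adsorbed fraction differed with and without UV in 261 genes by the interaction test.

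The genes called between the adsorbed fraction with UV and untreated arrays were weighed first. Against the untreated arrays of the first scan alone, these 1792 genes kept a median of 75.7% of their change (lower quartile 58.3%), which argues against the second-scan arrays as the whole source, but none was called: the median size fell from 0.95 to 0.69, with a standard error of 0.28 before and 0.30 after, so a smaller change and fewer arrays both entered. Under quantile normalization a median of 96.4% of the change was kept, which argues against the percentile scaling. The slide stays open, since with it as a block the median size was 0.56 and no gene was called, and so does an effect of the treatment, which may be the source of what was kept.

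HUG1 and RNR3, genes induced by DNA damage, were high on some arrays of several groups. Untreated arrays of a single slide differed in HUG1 by up to 6.66 and in RNR3 by 4.49 (replicates 7 and 8 on slide A), which argues against slide or scan; HUG1 was the dimmest probe above background on replicate 7, but RNR3 stood far above it there (-3.23 against -7.32). Only 3 of 12 arrays with UV lay above the highest array without UV, which argues against UV as the labels give it. For 2 arrays of other groups, replicates 1 and 4 of the non-adsorbed fraction without UV, the nearest array was one of the adsorbed fraction with UV. Untreated replicate 8 was nearest to that replicate 4 (0.241) and lay 0.247 from replicate 2 of the adsorbed fraction with UV. The nearest array of its own group lay 0.568 away. It was kept in every comparison against untreated yeast, and without it 2229 genes were called for the adsorbed fraction with UV. Exchanged or mixed samples could give such distances, as a hypothesis that these data alone cannot settle. Differences between cultures that the labels do not record were not tested. Replicate 1 of the adsorbed fraction with UV lacked the HUG1 level of its group. It shared the group's low HO (-4.65, others -3.31 to -2.67), histones (-1.38) and cell separation genes (-0.75). Its nearest array was of another group, replicate 1 of UV only (0.858), against 0.921 for the nearest of its own group. It thus lay far from every array, and whether it took part in an exchange is not settled here.

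The genes called between the adsorbed fraction without UV and the untreated arrays of slide C were weighed because the 2 groups lay in different array rows. On slides A and B, the difference between rows was a median of -13.3% and 4.08% of the change, which argues against the array row. Of the called genes, 20.0% lay in the lowest quartile of intensity. Dim genes may vary more and pass less often whatever the source, so this share cannot decide about the dimmer untreated arrays. On all arrays, normexp background correction turned 465 higher and 519 lower genes into 493 and 186. The median change of all genes went from -0.04 to 0.27, so background and dimness stay open. An effect of the adsorbed particles may be the source, as a hypothesis, and handling that differed between the 2 groups was not tested and stays open.

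Other splits of the same arrays were used to ask whether chance could give as many genes. For the adsorbed fraction without UV within slide C, where both groups had 4 arrays, 1 of 35 splits called as many as 1326 genes (the highest other 0). This argues against chance, but it is the smallest share that 35 splits allow, and the test was added after the result was seen. The real split also followed the array rows, so the splits alone cannot tell the group from other differences between the rows. The fractions with UV lay in equal numbers on each slide (1 of 35; 472 against 1), but the splits that keep this balance are too few for a share under 0.05, the others exchange slides as well, and no gene was called by limma without replicate 3 of either fraction, so nothing is said of chance there. In 4 other comparisons the splits exchanged arrays across slides that held the groups unequally, so few splits with as many genes cannot tell the group from the slide. These are the adsorbed fraction with UV against untreated (2 of 100; 1792 against 1803, where the other split exchanged replicate 2 for untreated replicate 1; 0 genes by limma with the slide as a block, 1191 at an unadjusted p below 0.05), the adsorbed fraction without UV on all arrays (1 of 100; 984 against 734, in a split that followed slide C; 1380 with the slide as a block), the interaction in the adsorbed fraction (1 of 100; 261 against 239; 773 with the slide as a block) and the fractions without UV (1 of 35; 1061 against 0; 49 with the slide as a block). For the adsorbed fraction against UV only (1 of 35; 1 against 0) the single gene was lost on leaving out any 1 of at least 7 arrays, so the splits carry no conclusion. Where no gene was called, every split calls as many, so the shares say nothing about chance: the non-adsorbed fraction with UV (100 of 100; highest other 686), without UV (100 of 100; 392) and UV only (100 of 100; 1089) against untreated, the non-adsorbed fraction against UV only (35 of 35; 14) and its interaction (100 of 100; 580). Such splits, with up to 1089 genes where the real one had 0, point to a structure of the arrays other than the groups.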

How the results depend on the processing

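First scan alone, leaving out the closest pair of arrays and leaving out the small slides D and E were chosen after the data were seen; the causes of the changes below were not tested. For the adsorbed fraction with UV against untreated, 1792 genes became 855 with normexp, 833 with only the groups compared, and 0 with the slide as a block or the first scan alone; leaving out arrays gave 683 to 2229. For the adsorbed fraction without UV, 984 became 355 with the replicate number as a block and 1588 without the small slides (229 to 1124 leaving out arrays), with 493 higher and 186 lower under normexp. UV only went from 0 to 1 with quantile normalization or the authors' table and to 642 without the small slides (0 to 697). For the fractions with UV, 472 became 119 with normexp, 1572 with the slide as a block, 123 with only the groups compared, 781 without the closest pair, and 0 with the first scan alone or without the small slides (0 to 857). For the fractions without UV, 1061 became 605 with normexp, 49 with the slide as a block, 542 without the closest pair and 1731 without the small slides (415 to 901). For the adsorbed fraction against UV only, 1 became 9 with quantile normalization or only the groups compared, 79 in the authors' table, 4 with the replicate number as a block, 61 without the closest pair, and 0 with the slide as a block or the first scan alone (0 to 187); without the small slides 1 gene was called, but NIT1 and not BUD4 (-1.58). The interaction in the adsorbed fraction went from 261 to 99 with normexp, 773 with the slide as a block, 49 with the replicate number as a block, 143 without the closest pair and 855 without the small slides (98 to 593). The other 4 comparisons stayed at 0 in limma under the alternatives listed and with any array left out. At an unadjusted p below 0.05 they had 560, 604, 20 and 422 genes. Fits within 1 slide that left 1 array in a group are not counted here, since other groups gave their spread. The 144 calls of lists became 0 with an estimated correlation and 147 with the slide as a block. The sign of the median turned for 6 called lists with normexp, 6 with the slide as a block, 6 without the small slides and 3 of 114 on the first scan alone. Of the 6 without the small slides, 5 lay in the adsorbed fraction against UV only and 1, cytosolic ribosomal proteins (-0.60 to 0.14), in the interaction of the adsorbed fraction.

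Replicate numbers did not pair the arrays: deviations of arrays with one number correlated at a median of 0.035 (-0.60 to 0.82), and 5 of 24 arrays were nearest to their own number, so the counts with the replicate number as a block rest on a shared number alone. Of 266 named results that had passed, the call was lost in 110 with normexp, 136 with the slide as a block, 51 with the replicate block, 72 with only the groups compared, 7 with quantile normalization, 5 in the authors' table, 83 without the small slides, 18 without the closest pair and 160 of 160 on the first scan alone. Sign turned under normexp for SPS22 (-0.27), THI13 (-0.54) and ATG29 (-0.068) in the adsorbed fraction with UV, and between the fractions without UV for RPC17 (0.28), RPC53 (0.063), THI11 (0.90), THI72 (0.41), SNO2 (0.69) and THI13 (1.66). With the slide as a block it turned for RPN3 (-0.035, and -0.057 on the first scan alone) in the adsorbed fraction with UV, and between the fractions without UV for SRL1 (-0.15), PAI3 (0.30), RPN3 (0.23), RPT4 (0.25) and THI72 (0.27). STI1 in the non-adsorbed fraction with UV, not called, went to -0.21 with the slide as a block and -0.074 on the first scan alone. No call was lost with a filter at 24 arrays (252 named results) and 3 were lost without a filter.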

Other observations

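The lists, arrays and genes of this part were all chosen after their values were seen. Within slide C alone, 2 lists that had not been called on all arrays shifted in the adsorbed fraction without UV (4 against 4 arrays). Of 18 measured genes of the Zap1 zinc regulon, 9 fell and 2 rose (10 and 2 adjusted over the list alone), with a median of -0.84 (camera adjusted p = 3.7e-04, adjusted p = 0.433 with an estimated correlation). Of 22 genes of the hypoxic and anaerobic list, 6 rose and none fell (6 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.0223, adjusted p = 0.424 with an estimated correlation). A 3rd list called only there, of lipid synthesis under Ino2/4, had 3 of 18 genes that fell and a median of -0.29 (camera adjusted p = 0.0223, adjusted p = 0.834 with an estimated correlation).

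Arrays often lay closer to another group than to their own. Of 28 arrays, 19 were nearest to an array of another group, and of the 20 first-scan arrays 18 were. The median absolute difference between arrays was 0.587 within a group and 0.679 between groups. Replicate 2 of the adsorbed fraction with UV and replicate 4 of the non-adsorbed fraction without UV differed least (0.113). Replicate 1 of the non-adsorbed fraction with UV (slide D) and untreated replicate 1 (slide E) were nearest to replicate 4 of UV only (slide E). They lay 0.203 and 0.209 from it, against 0.565 and 0.617 from the nearest array of their own groups. Replicate 1 of the adsorbed fraction with UV lay 0.858 from its nearest array, replicate 1 of UV only.

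GAR1 and BUD23 were low together on some of the irradiated arrays. BUD23 stood at -3.11, -0.57, -2.97 and -1.02 on replicates 1 to 4 of UV only, and at -0.95, -3.03, -0.13 and 0.14 on those of the non-adsorbed fraction with UV. GAR1 stood at -2.66, -1.16, -2.29 and 0.21 on the former and at -0.17, -2.40, -0.17 and 0.10 on the latter. Replicates 1 and 3 of UV only and replicate 2 of the non-adsorbed fraction with UV were each nearest to another array among them. They shared low ATS1 (-2.75, -3.26 and -3.09) and SHR5 (-2.17, -3.12 and -2.93), and HUG1 at -1.80, -2.24 and -2.23. BUD23, ATS1 and SHR5 were about as low there as in the adsorbed fraction without UV, but GAR1 was not (-5.64 to -3.98 in that fraction). The mitochondrial gene COB stood at -3.69 to -4.29 on replicates 2 to 4 of the adsorbed fraction with UV, at -3.74 and -3.64 on replicates 1 and 4 of the non-adsorbed fraction without UV, and at -3.52 on untreated replicate 8. The other untreated arrays lay between -1.76 and 0.81 in COB.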
